A study of Mus musculus with 20 samples.

How the data were processed

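RNA sequencing measured gene expression in the hippocampus of male C57BL/6 mice, a widely used inbred laboratory strain. The mice were 5 or 24 months old and had either been left without intervention (control) or been kept in an enriched environment, the usual name for housing with more space, objects and company than a standard cage. Each of the 4 groups held 5 libraries, 20 in all. What the enriched housing held and how long it lasted is not given in the sources used here. The labels name no batch, litter or pairing, so no block was fitted, and replicate numbers only name a library. No label states that each library came from its own animal. They are called mice here, and if any shared an animal the p-values would measure only the spread between these samples.

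Per the labels' protocols, total RNA was made into libraries with a TruSeq RNA kit of the v2 chemistry, which does not mark the strand. Per the submitters' processing notes, CASAVA 1.8.2, STAR 2.4.1d and featureCounts 1.4.6-p4 were used with the genome build GRCm38. The annotation release, the strand setting and the handling of reads with several matches are not given in the sources used here. Genes that overlap another gene, lie antisense to one or share sequence with one can therefore have exchanged reads in the counting. The authors deposited a table of counts per gene, which are whole numbers with no normalization, and a table named RPKM, which scales reads to gene length and library total. The count table held 47729 genes, of which 47224 were paired with a symbol. The deposited RPKM values were compared with the counts over 12780 genes with at least 50 counts in every library. The gene length that a count and an RPKM value imply varied between libraries with an SD of 0.248 on the log2 scale when each library's own total was used. It varied with an SD of 0.000238 when the library totals were instead repeated in turn down the list of genes. The total behind a deposited RPKM value thus differed from the library's own by a factor of 0.698 to 1.43, so the deposited RPKM values are a score made by the authors rather than RPKM of these libraries, and served only as an alternative.

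Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with enough counts in at least a group's worth of libraries were kept (filterByExpr, default minimum count 10), which left 17527 genes, 17471 of them with coordinates. Library sizes were scaled by TMM, a quasi-likelihood model with 1 coefficient per group was fitted over all 20 libraries, and 6 contrasts were tested. These were enriched against control housing at 5 months, at 24 months and as the mean of both ages, 24 against 5 months in control and in enriched mice, and the difference of the enrichment effect between both ages. P-values were adjusted by the method of Benjamini and Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Log2 fold changes are given with a standard error, the size of the change divided by the square root of its F statistic. CPM values, counts scaled to a common library total, used the TMM-scaled library sizes. Those of Xist, Ddx3y, Eif2s3y and Uty used the total counts without TMM. Coordinates and gene types come from an Ensembl-based annotation of GRCm38 (GENCODE M21).

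A set of 39 gene lists for brain cell types, neighbouring tissues and pathways was tested with camera of limma 3.58.1 on voom values, with a preset correlation between genes of 0.01. Adjusted p-values run over the lists of a contrast. The same test was run with an estimated correlation. The level of a list in a mouse was the mean log2 CPM of its tested members (prior count 2), and levels were compared by exact two-sided permutation of the mice. With 5 mice against 5 there are 252 assignments and the smallest p is 0.00794; for both ages together there are 63504 assignments and the smallest p is 3.15e-05. A count of members "adjusted over the list alone" adjusts p over that list's genes instead of all genes tested. Correlations between fold changes were set against relabelings of the mice, since genes are not independent replicates.

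The groups, the contrasts, the tests, the gene lists, most alternatives and the rule for naming genes were set before the data were examined. The rule named, per contrast, the 12 largest rises and 12 largest falls among called genes with a mean of at least 1 CPM, no overlap between the groups and an established symbol. Where fewer passed, all called genes were named, with the 5 rises and 5 falls of smallest p as values only. From each list up to 4 members of smallest p could be named. Genes named outside this rule are stated as such.

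The statistics were tested on simulated counts with 50 genes changed at each of 4 sizes per contrast, drawn from the real means and library sizes. In control mice between both ages (17391 genes), 14, 60, 78 and 90 percent of genes changed 1.25, 1.5, 2 and 3 times were recovered, and 5 unchanged genes were called. In enriched mice between both ages (17383 genes) the shares were 16, 46, 74 and 98 percent, with 8 unchanged genes called. For enrichment at 5 months (17376 genes) they were 20, 60, 74 and 96 percent with 6 unchanged genes called, and at 24 months (17407 genes) 20, 56, 80 and 92 percent with 1. For the mean of both ages (17412 genes) they were 36, 74, 88 and 98 percent with 8 unchanged genes called, and for the difference of the effects (17401 genes) 6, 36, 66 and 90 percent with 5. No recovered change had the wrong sign. Each gene was drawn on its own, without the variation shared between genes that the real libraries show. The shares recovered and the unchanged genes called can therefore differ in the real data.

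Alternatives were RLE scaling, DESeq2 1.42.0, limma-voom, no expression filter, a mean of at least 1 CPM, 1 surrogate variable (sva 3.50.0), limma on log2(RPKM + 0.1) with the deposited RPKM values, only the compared groups in the fit, and leaving out each library in turn. Added after the data were seen were a robust fit, RPKM with each library's own total put back, choroid plexus and meningeal list levels as covariates, and a fit without 2 libraries that stand apart (mouse 4 of the 5-month enriched group and mouse 5 of the 24-month controls). All 20 libraries entered the main tests. Without the 2 libraries the gene lists were tested by camera with the preset correlation only.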

Results

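Hippocampal RNA was profiled in 20 male mice, 5 in each combination of 2 ages (5 and 24 months) and 2 housings (control and enriched environment). Total counts ranged from 26065565 to 37366991 in 5-month controls and from 29650393 to 36598273 in 5-month enriched mice. They ranged from 28510759 to 36421096 in 24-month controls and from 28148334 to 37178680 in 24-month enriched mice. Between 23387 and 25137 genes had at least 1 count. Genes of the Y chromosome were present in every library (Ddx3y 35.8 to 72.4 CPM, Eif2s3y 25.5 to 59.8 CPM, Uty 16.3 to 26.7 CPM) and Xist, expressed in females, lay between 0.0363 and 0.384 CPM, as the male label requires. No pair of libraries within a group was a repeat: over 40 pairs, the chi-square of their counts per degree of freedom was 6.93 to 62.3. The median standard error of a log2 fold change was 0.112 in comparisons of 2 groups, 0.0791 for the mean enrichment effect and 0.158 for the difference of effects.

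Markers of tissues that border the hippocampus varied widely within groups. The choroid plexus list had levels (mean log2 CPM) of 0.936 to 5.02 in 5-month controls, 1.22 to 3.91 in 5-month enriched mice, 1.05 to 4.27 in 24-month controls and 1.15 to 2.01 in 24-month enriched mice. Its most abundant member, the thyroxine carrier Ttr, ran from 32.2 to 3980 CPM among 5-month controls. Mouse 4 of the 5-month enriched group stood apart in interferon-induced genes, with Ifit3 at 66.2 CPM against 2.51 to 8.07 CPM in the other 19 libraries. Mouse 5 of the 24-month controls held liver transcripts, with albumin (Alb) at 68.2 CPM against 1.6 to 17.4 CPM elsewhere.

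The first question was what ageing changed in control mice. Genes used in cell division were among those that fell: Top2a, the topoisomerase of proliferating cells, went from 1.99 ± 0.275 CPM at 5 months to 0.453 ± 0.215 CPM at 24 months (mean ± SD, n = 5 each), and the mitotic genes Cenpf and Pbk fell with it. Gpr17, a receptor of oligodendrocyte precursors on their way to differentiation, dropped from 55.7 ± 4.37 to 26.1 ± 6.06 CPM. Upk1b, a tetraspanin first described in the urinary tract, rose from 1.43 ± 0.328 to 3.45 ± 0.816 CPM, and Spag6, a protein of the ciliary axoneme, from 2.78 ± 0.351 to 5.68 ± 0.578 CPM. Pcdhb9, a protocadherin by which neurons recognise each other, rose from 13.6 ± 1.59 to 23.9 ± 3.97 CPM.

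edgeR's quasi-likelihood test called 12 genes higher and 4 lower at 24 months, and 1469 genes had an unadjusted p under 0.05. In each contrast 876 of the genes tested would be expected under 0.05 by chance. DESeq2 called 53 and 25 and a fit with 1 surrogate variable 19 and 8, each with all 16 genes among them. The falls on the log2 scale (± SE) were -2.11 ± 0.30 for Top2a (adjusted p = 0.0026), -1.09 ± 0.13 for Gpr17 (adjusted p = 0.000665) and -3.09 ± 0.48 for Pbk (adjusted p = 0.00472). Cenpf dropped 2.38-fold (adjusted p = 0.00284). Among the rises were Upk1b (1.26 ± 0.21, adjusted p = 0.0102), Spag6 (1.03 ± 0.13, adjusted p = 0.000665) and the leukocyte actin-binding gene Lsp1 (0.99 ± 0.16, adjusted p = 0.00587). Others were Pcdhb2 (0.92 ± 0.18, adjusted p = 0.0461), the peptidase gene Naalad2 (0.89 ± 0.15, adjusted p = 0.0164), Pcdhb9 (0.81 ± 0.11, adjusted p = 0.00139) and the actin-bundling gene Espn (0.66 ± 0.13, adjusted p = 0.0416). The calcium-release protein gene Trdn also rose (1.74 ± 0.32, adjusted p = 0.0323), from 0.129 ± 0.04 to 0.444 ± 0.116 CPM. The other called genes were A530053G22Rik (3.84), Gm38340 (1.69), AC149090.1 (1.27) and Gm10654 (1.08). Gm38340 overlaps Tshz3 on the same strand and AC149090.1 lies on an unplaced scaffold, so both are uncertain. Fcrls, a microglial receptor, at -0.76 ± 0.16 (adjusted p = 0.0601), and Kif11, the spindle kinesin, at -0.81 ± 0.17 (adjusted p = 0.0601), missed the threshold. In GRCm38, Top2a (ENSMUSG00000020914) lies on chromosome 11 from 98992943 to 99024189 and Gpr17 (ENSMUSG00000052229) on chromosome 18 from 31942997 to 31949636. Upk1b (ENSMUSG00000049436) lies on chromosome 16 from 38773184 to 38800328 and Spag6 (ENSMUSG00000037708) on chromosome 2 from 18694032 to 18750413. Gpr17 overlaps Lims2 on the opposite strand, which had 9.28 CPM on average against 38.5 CPM for Gpr17. Without mouse 2 or mouse 5 of the 5-month controls, or mouse 3 of the 24-month controls, 6 genes were called higher and 10 of the 16 calls were kept. Without mouse 2 of the 24-month controls 7 were called higher and 11 calls were kept. The deposited RPKM values gave 13 higher and 2 lower, and a fit of the compared groups alone 15 and 9.

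**Figure D1:**
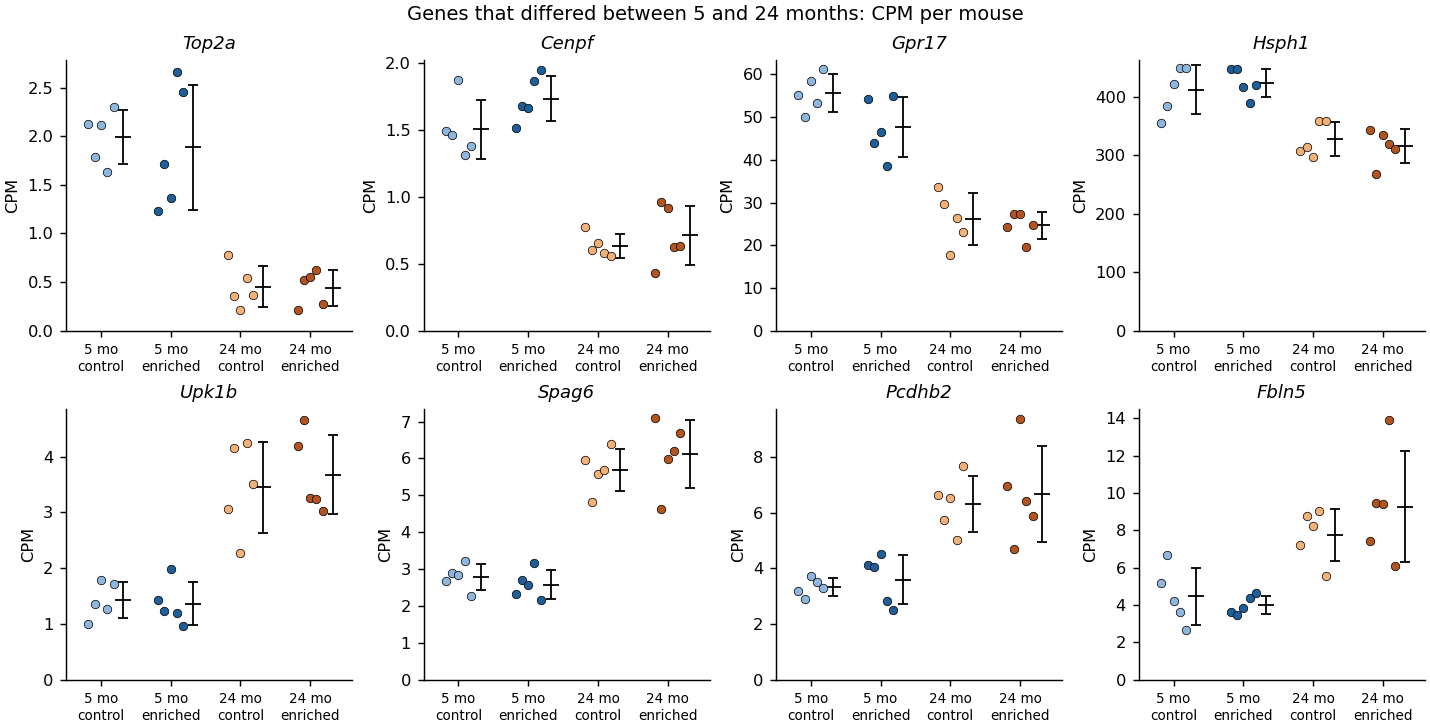
CPM (vertical axis) of 8 genes in each mouse of the 4 groups (horizontal axis); points are mice and the bars give mean ± SD (n = 5). Top2a, Cenpf, Gpr17 and Hsph1 lie lower at 24 than at 5 months and Upk1b, Spag6, Pcdhb2 and Fbln5 higher; in control mice Hsph1 (adjusted p = 0.127) and Fbln5 (adjusted p = 0.237) did not pass edgeR's test.

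As a group, genes of neurogenesis and immature neurons were lower in old control mice: 28 of 31 tested members lay below 0, with a median of -0.32. Over all genes tested 2 members fell (Top2a and Cenpf), and 11 fell when adjusted over the list alone. The list also holds genes of cell division, such as Top2a, Cenpf and Cdk1, so it does not measure immature neurons alone. The immature-neuron gene Dpysl3 was at -0.32 ± 0.08 (adjusted p = 0.163) and Igfbpl1, of newborn neurons, at -2.73 ± 0.76 (adjusted p = 0.246). The list level dropped by 0.494, camera's adjusted p was 1.19e-14, and the adjusted p was 0.000332 with an estimated correlation. The exact permutation test gave p = 0.00794, the smallest it can give, and an adjusted p of 0.103 over the 39 lists.

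Chaperones of the endoplasmic reticulum, which fold secreted proteins, were lower too, with 16 of 17 below 0, a median of -0.22, 0 passing over all genes and 10 adjusted over the list alone. Pdia4 was at -0.39 ± 0.09 (adjusted p = 0.127). camera called this list (adjusted p = 1.04e-10; adjusted p = 0.207 with an estimated correlation) and the heat shock list (median -0.12, 1 member adjusted over the list alone; adjusted p = 7.49e-06, and 0.207 as the adjusted p with an estimated correlation). Immediate early genes, which neuronal activity switches on, lay below 0 in 28 of 30 (median -0.23, none adjusted over the list alone; camera adjusted p = 1.49e-05, adjusted p = 0.729 with an estimated correlation). In the oligodendrocyte precursor list, 16 of 19 lay below 0, with Gpr17 past the threshold over all genes and 2 adjusted over the list alone (camera adjusted p = 0.000832; adjusted p = 0.456 with an estimated correlation). The matrix genes of perineuronal nets had 14 of 18 below 0 and 3 lower adjusted over the list alone, among them the lectican Ncan at -0.33 ± 0.10 and the matrix protein Tnc at -0.72 ± 0.22 (camera adjusted p = 0.00705; adjusted p = 0.45 with an estimated correlation).

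Some immune and glial lists were called higher in old control mice. Of 28 activated microglia genes 21 lay above 0 (median 0.18), with the receptor Clec7a at 1.64 ± 0.41 (adjusted p = 0.158). All 18 genes of MHC class I antigen presentation lay above 0 (median 0.25). Of 24 reactive astrocyte genes 16 lay above 0 (median 0.13), with 3 adjusted over the list alone, among them the complement gene C4b at 1.46 ± 0.36 (adjusted p = 0.138), which went from 38 ± 4.34 to 104 ± 16.8 CPM. camera called these lists (adjusted p = 0.000832, 0.000966 and 0.0231; adjusted p = 0.74 for each with an estimated correlation), and also the complement, ribosomal protein and circadian clock lists as higher. Further lists were called lower by camera, of bordering tissues, vessels and neurons: the red blood cell list (5 of 5 below 0, median -0.50), the ependyma list (17 of 17, median -0.47), meningeal fibroblasts (15 of 18, median -0.40), pericytes (12 of 15), endothelium (15 of 20) and CA1 to CA3 pyramidal neurons (18 of 23). The circadian clock list lost its call without the 2 libraries that stand apart (adjusted p = 0.0547). With the preset correlation 18 lists were called, 6 higher and 12 lower. The neurogenesis list alone held with an estimated one, the other 17 having an adjusted p of 0.207 to 0.89 with an estimated correlation. The remaining 21 lists were not called, among them interferon response (median -0.02) and the choroid plexus (median -0.68, camera adjusted p = 0.116).

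The same ages were compared in enriched mice. Top2a fell from 1.89 ± 0.641 to 0.438 ± 0.182 CPM and Gpr17 from 47.6 ± 6.99 to 24.7 ± 3.17 CPM (mean ± SD, n = 5 each). The heat shock protein gene Hsph1 dropped from 424 ± 24.4 to 315 ± 29.2 CPM and Hspa5, the main chaperone of the endoplasmic reticulum, from 318 ± 66.9 to 224 ± 26.8 CPM. Spag6 rose from 2.58 ± 0.386 to 6.12 ± 0.935 CPM, Fbln5, a gene of elastic fibres, from 4 ± 0.493 to 9.28 ± 2.97 CPM, and Lin28b, an inhibitor of let-7 microRNA maturation, from 3.82 ± 0.501 to 8.01 ± 1.13 CPM. The insulin-regulated glucose transporter Slc2a4 rose from 0.585 ± 0.151 to 1.55 ± 0.475 CPM.

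edgeR called 60 genes higher and 27 lower, with 2063 at an unadjusted p under 0.05, against 160 and 114 with DESeq2 and 104 and 68 with 1 surrogate variable. Besides Top2a (-2.08 ± 0.30, adjusted p = 0.0018), the largest falls under the naming rule were Cenpf (-1.27 ± 0.18, adjusted p = 0.00165), Gpr17 (-0.95 ± 0.13, adjusted p = 0.00165), Kif11 (-0.83 ± 0.16, adjusted p = 0.0247) and the DNA repair gene Brca1 (-0.81 ± 0.17, adjusted p = 0.0381). The ciliary gene Ccdc151, the inositol transporter Slc5a3, the long noncoding RNA Dubr, Tsga10, the Polycomb gene Cbx8, Hsph1 (-0.43 ± 0.08, adjusted p = 0.0181) and Rbm28 fell by 0.60 to 0.41 on the log2 scale, with adjusted p-values of 0.0181 to 0.0486. Rises were Upk1b (1.43 ± 0.21, adjusted p = 0.0018), Fbln5 (1.21 ± 0.22, adjusted p = 0.0139), the monooxygenase Fmo2 (1.11 ± 0.24, adjusted p = 0.0381), Lin28b (1.06 ± 0.15, adjusted p = 0.00165) and the organelle transport gene Mlph (1.05 ± 0.13, adjusted p = 0.000911). Slc2a4 rose 2.64-fold (adjusted p = 0.00362) and Spag6 2.37-fold (adjusted p = 8.73e-05). Pcdhb2, Pcdhb8, Rnf207, the phospholipase Pla2g4e and Pcdhb6 rose by 0.81 to 0.89, with adjusted p-values of 0.00198 to 0.0311. Slc5a3 overlaps Mrps6 on the same strand and Rnf207 overlaps Icmt on the opposite one, so both are uncertain. Of the 90 genes called in either housing, 49 overlap another annotated gene, 23 of them a tested one, and are uncertain to that extent. The numbers of higher and lower genes moved with single libraries. They were 155 and 83 without mouse 4 of the 5-month enriched group (81 of the 87 calls kept). They were 21 and 6 without its mouse 1, 19 and 7 without mouse 2, 30 and 9 without mouse 3 and 39 and 15 without mouse 5. Without mice 3, 4 and 5 of the 24-month enriched group in turn they were 31 and 13, 27 and 6, and 31 and 7. These 7 fits kept 26 to 43 of the 87 calls. The deposited RPKM values gave 9 higher and 1 lower, and covariates for the choroid plexus and meningeal levels left 19 higher and 6 lower. A fit of the compared groups alone gave 12 and 3, and the fit without both libraries that stand apart 151 and 75.

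In enriched mice the neurogenesis list again had most members below 0 (27 of 31, median -0.27). It held 4 falls over all genes (Top2a, Cenpf, the mitotic kinase gene Cdk1 at -1.93 ± 0.35 and Dpysl3 at -0.38 ± 0.08) and 15 adjusted over the list alone. Its level dropped by 0.499 (camera adjusted p = 6.75e-13; adjusted p = 0.000745 with an estimated correlation; exact p = 0.00794, adjusted 0.155). Endoplasmic reticulum chaperones held 3 falls over all genes, in Hspa5 (-0.51 ± 0.11), Pdia4 (-0.45 ± 0.09) and Pdia6 (-0.44 ± 0.09), and 12 of 17 adjusted over the list alone (camera adjusted p = 2.72e-10; adjusted p = 0.217 with an estimated correlation). The heat shock list held 2 falls over all genes, in Hsph1 and Chordc1 (-0.37 ± 0.08), and 9 of 20 adjusted over the list alone (camera adjusted p = 1.19e-09; adjusted p = 0.0548 with an estimated correlation). Circadian clock genes lay above 0 in 14 of 17 with 5 higher adjusted over the list alone (camera adjusted p = 5.94e-05; adjusted p = 0.0548 with an estimated correlation). Ciart, a repressor of the clock, was at 0.62 ± 0.16 (adjusted p = 0.0947). Reactive astrocyte genes held 2 rises over all genes, Fbln5 and the oncostatin M receptor Osmr (0.72 ± 0.14, adjusted p = 0.0233), and 7 of 24 adjusted over the list alone (camera adjusted p = 0.000193; adjusted p = 0.875 with an estimated correlation). Activated microglia (22 of 28 above 0), MHC class II, complement, meningeal and glucocorticoid-responsive lists were also called higher. Ependyma (17 of 17 below 0, median -0.72) and choroid plexus genes (23 of 23 below 0, median -1.44) were called lower. All of these had an adjusted p of 0.708 to 0.875 with an estimated correlation. The other 27 lists were not called. Without the 2 libraries that stand apart, 12 lists were higher and 9 lower by camera with the preset correlation. The interferon (adjusted p = 2.66e-09) and MHC class I lists (adjusted p = 1.25e-11) were now among the higher ones. Mouse 4 of the 5-month group was left out after its levels of these lists were seen, so neither p is an independent test. The meningeal and glucocorticoid-responsive lists lost their calls without the same 2 libraries (adjusted p = 0.0781 for each). In the 24-month enriched group the meningeal level was highest in mice 3 and 4 (4.75 and 4.439, others 3.498 to 3.749). So was the MHC class II level (1.461 and 1.338, others 0.4376 to 0.8295).

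**Figure D2:**
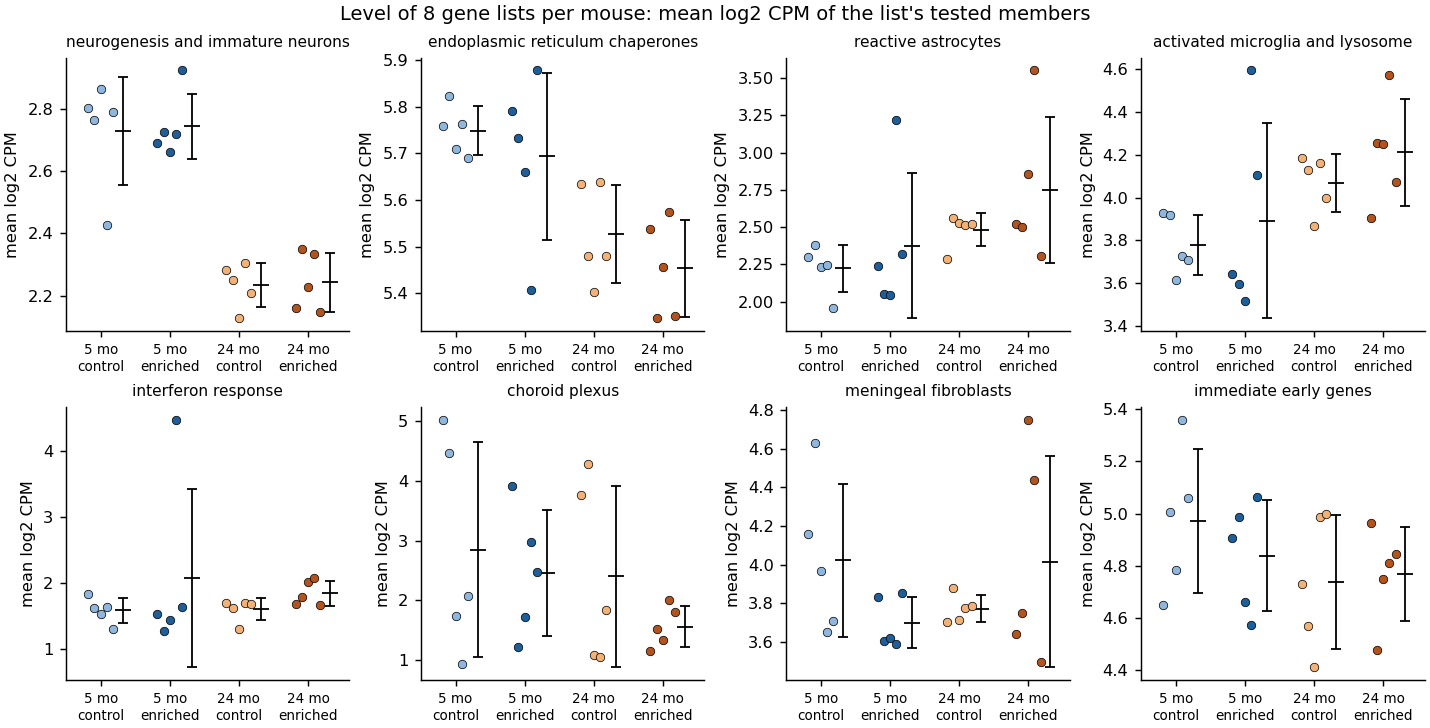
Level of 8 gene lists (mean log2 CPM of the tested members, vertical axis) in each mouse of the 4 groups (horizontal axis); points are mice, bars mean ± SD (n = 5). The neurogenesis list lies near 2.73 and 2.74 in both groups at 5 months and near 2.24 in both at 24 months, while 1 mouse of the 5-month enriched group reaches 4.48 in the interferon list against 1.27 to 1.63 in the other 4.

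Both ageing comparisons share no mouse. Of the 12 genes called higher in control mice 10 were also called in enriched mice, where independent lists would share 0.0411, and of the 4 called lower 3 were (0.00616). All 87 genes called in enriched mice had the same sign in control mice. Ddb2, a DNA damage sensor picked after its values were seen, was closest to 0 in control mice (adjusted p = 0.998), against 0.39 ± 0.08 in enriched mice. It overlaps Acp2 on the opposite strand, which had 54.6 CPM on average against 6.96 CPM for Ddb2, so its value is uncertain. The difference between both housings was itself tested as the difference of effects, and 7 of the 87 genes had an unadjusted p under 0.05 in it, none passing adjustment.

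**Figure D3:**
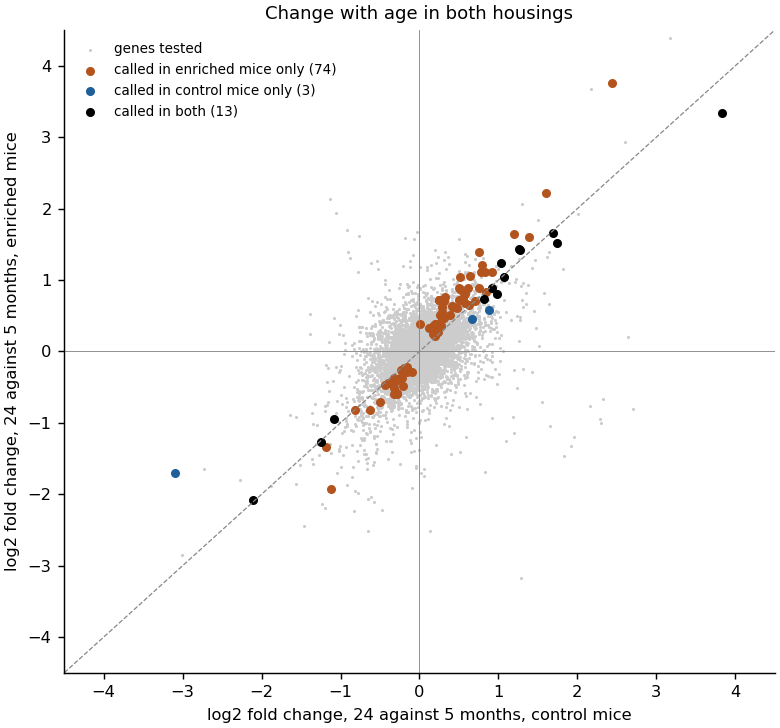
Log2 fold change from 5 to 24 months in control mice (horizontal axis) and enriched mice (vertical axis) for each of 17527 genes; large points were called in both housings (13), in enriched mice only (74) or in control mice only (3), and the dashed line marks equal change. Called genes lie in the quadrants where both changes have 1 sign.

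The beta protocadherins, single-exon genes in a row on chromosome 18 (37264938 to 37524479) whose proteins give neurons surface identities, were singled out after their values were seen. All 22 were higher at 24 months in enriched mice (median 0.34) and 20 of 22 in control mice (median 0.24), and under the other settings 19 to 22 and 19 to 21 were. In enriched mice 7 rose (Pcdhb1 at 1.65 ± 0.26, Pcdhb2, Pcdhb3 at 0.71 ± 0.16, Pcdhb5 at 0.68 ± 0.12, Pcdhb6, Pcdhb8 and Pcdhb9) and in control mice Pcdhb2 and Pcdhb9. With a library left out, 5 to 8 were called in enriched mice. In control mice 1 was called with any library left out except mouse 3 at 5 months and mouse 4 at 24 months, which left 2. In enriched mice 3 were called with the choroid plexus and meningeal covariates, and 1 with the deposited RPKM values or the compared groups alone. Each of the 7 overlaps Gm42416, Gm37013 and Gm37388 on the same strand, which were not among the genes tested, so their values are uncertain. All 7 lie among the first 9 genes of the row. The row was divided at the last called gene, so the higher median of the first 9 (0.71 over both housings, against 0.21 for the other 13) is in part a product of that choice. Their transcripts share up to 64.2 percent of 50-base words with another gene (Pcdhb12), but at most 8.75 percent among the first 9.

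**Figure D4:**
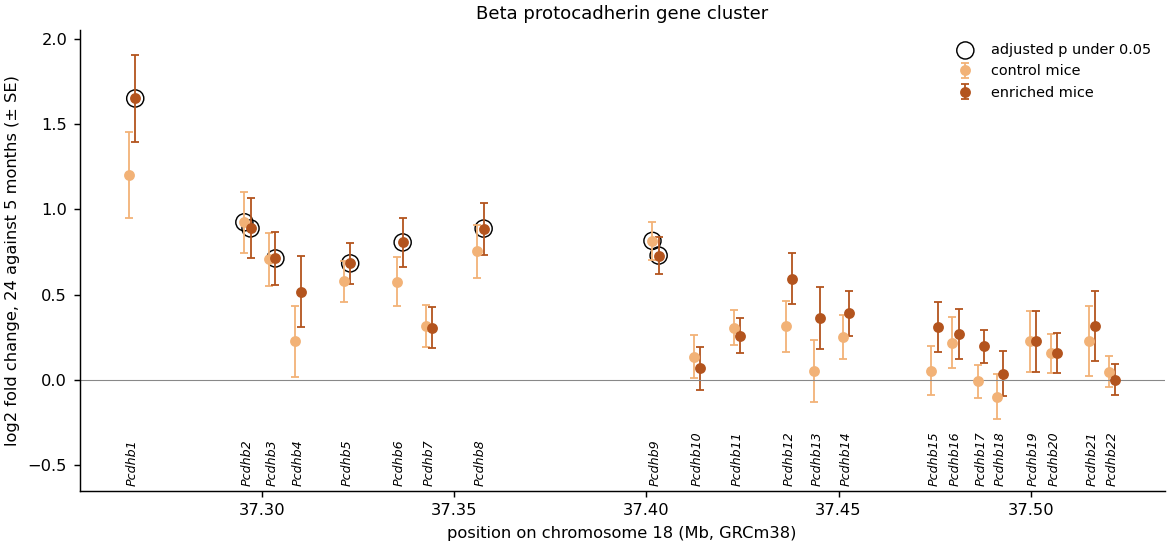
Log2 fold change from 5 to 24 months ± SE (vertical axis) of the 22 beta protocadherin genes against their position on chromosome 18 in Mb (horizontal axis), in control and enriched mice; rings mark an adjusted p under 0.05. Of the 22 genes 7 are called in enriched mice and 2 in control mice, and the genes with rings lie between Pcdhb1 and Pcdhb9.

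Enrichment at 5 months was tested next. The gene with the smallest p among those higher was Neurod4, a neuronal transcription factor, at 0.270 ± 0.12 CPM in control and 0.583 ± 0.135 CPM in enriched mice (log2 1.06 ± 0.28, adjusted p = 1). Npy, the neuropeptide Y gene of inhibitory neurons, stood at 33.8 ± 5.8 and 44.5 ± 6.89 CPM (0.40 ± 0.11, adjusted p = 1). On the lower side were Depp1 (-1.80 ± 0.48) and Slco1c1, a thyroid hormone transporter of brain vessels (-0.31 ± 0.09), both with an adjusted p of 1. edgeR called 0 genes, with 450 at an unadjusted p under 0.05, fewer than the 876 expected by chance. DESeq2 called 0 (413 unadjusted) and limma-voom 0 (380 unadjusted). With the deposited RPKM values 1562 had an unadjusted p under 0.05 in limma's test, and 0 were called. Without mouse 5 of the 5-month enriched group 695 genes had an unadjusted p under 0.05, and 0 were called.

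All 30 interferon response genes lay above 0 at 5 months (median 1.19; 11 higher adjusted over the list alone), with Ifit1 at 2.30 ± 0.72 and Oasl2 at 2.19 ± 0.70, both with an adjusted p of 1 over all genes. camera called the list (adjusted p = 2.08e-06; adjusted p = 0.806 with an estimated correlation). The exact permutation test of the levels gave p = 0.841, and without mouse 4 of the enriched group and the liver-containing control the list was lower (camera adjusted p = 0.00672). That mouse was left out after its interferon levels were seen, so this camera value is no independent test. Dentate gyrus granule cell genes lay above 0 in 19 of 21 (median 0.15; camera adjusted p = 7.04e-05, adjusted p = 0.806 with an estimated correlation). Vessel and fibroblast lists lay below 0, with 22 of 25 collagen and basement membrane genes (median -0.19), 15 of 15 pericyte genes (median -0.23), 16 of 18 meningeal genes (median -0.33) and 19 of 20 endothelial genes (median -0.18). In all, camera called 13 lists, 6 higher (also MHC class I, ribosomal protein, oxidative phosphorylation and ependyma genes) and 7 lower (also red blood cell, immediate early and glucocorticoid-responsive genes), with an adjusted p of 0.695 to 0.806 with an estimated correlation. Without the same 2 libraries camera also put MHC class I genes (adjusted p = 0.262) and ribosomal protein genes (adjusted p = 0.879) lower rather than higher. The oxidative phosphorylation (adjusted p = 0.714), immediate early (adjusted p = 0.356) and glucocorticoid-responsive lists (adjusted p = 0.121) lost their calls there, while the vessel, fibroblast, red blood cell, ependyma and dentate gyrus lists kept theirs. No list passed the exact test.

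At 24 months, Hcst, a signalling adaptor of immune cells, had the smallest p, at 0.134 ± 0.0719 CPM in control and 0.382 ± 0.0515 CPM in enriched mice (log2 1.47 ± 0.29, adjusted p = 1), followed among the higher genes by the urokinase receptor Plaur (1.07 ± 0.26). Usp2, a deubiquitinase under clock control, was at 62.8 ± 4.88 and 75.4 ± 9.66 CPM (0.26 ± 0.07, adjusted p = 1). On the lower side, the liver genes Hpx (-1.43 ± 0.42) and Mup3 (-3.23 ± 0.95) were high in the control mouse with liver transcripts. edgeR called 0 genes, with 323 at an unadjusted p under 0.05; DESeq2 called 0 (317 unadjusted) and limma-voom 0 (298 unadjusted).

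All 23 choroid plexus genes lay below 0 in 24-month enriched mice (median -1.61), in which no mouse had the high levels found in 2 controls (camera adjusted p = 2.76e-06; adjusted p = 0.972 with an estimated correlation; exact p = 0.365). Reactive astrocyte genes lay above 0 in 23 of 24 (median 0.25), activated microglia genes in 23 of 28 (median 0.11) and interferon genes in 26 of 30 (median 0.23). Mouse 4 of the enriched group had the highest reactive astrocyte level (3.551, other enriched mice 2.308 to 2.86, controls 2.288 to 2.564). It was also highest in activated microglia genes (4.574, others 3.904 to 4.254, controls 3.866 to 4.185) and MHC class I genes (3.801, others 2.952 to 3.31, controls 2.85 to 3.336). In these 3 lists the other enriched mice overlapped the controls. Meningeal genes lay above 0 in 15 of 18 (median 0.30) with the collagen-binding proteoglycan Fmod at 1.53 ± 0.50 (adjusted p = 1), and endoplasmic reticulum chaperones below 0 in 14 of 17 (median -0.09). The meningeal level was high in mice 3 and 4 of the enriched group (4.75 and 4.439), while the other enriched mice (3.498 to 3.749) overlapped the controls (3.706 to 3.881). camera called 13 lists, 10 higher (also MHC class I and II, mitochondrially encoded, endothelial, astrocyte and homeostatic microglia genes) and 3 lower (also heat shock genes), each with an adjusted p of 0.972 with an estimated correlation. Without the 2 libraries that stand apart the astrocyte (adjusted p = 0.835), mitochondrially encoded (adjusted p = 0.188) and homeostatic microglia lists (adjusted p = 0.168) lost their calls. None passed the exact test.

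For the mean of both ages the smallest p-values belonged to Hcst (1.02 ± 0.21), Usp2 (0.23 ± 0.05) and Npy (0.30 ± 0.08) among the higher genes and Krtcap3 (-0.39 ± 0.10) and the complement gene C4a (-0.42 ± 0.12) among the lower ones, all with an adjusted p of 1. edgeR called 0 genes (559 at an unadjusted p under 0.05), as did DESeq2 (530) and limma-voom (450). camera called 9 lists higher and 5 lower, led by interferon (30 of 30 above 0, median 0.67) and choroid plexus genes (22 of 23 below 0, median -1.23), all with an adjusted p of 0.949 with an estimated correlation; without the 2 libraries that stand apart 2 were higher and 3 lower.

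Whether enrichment acted differently at both ages was tested as the difference of its effects, 24 minus 5 months. The macrophage gene Ms4a7 had the smallest p (1.85 ± 0.46), with Fmod next among fibroblast genes (2.61 ± 0.71), and the replication gene Fen1 was on the lower side (-0.80 ± 0.25), all with an adjusted p of 1. edgeR called 0 genes (278 at an unadjusted p under 0.05), as did DESeq2 (244) and limma-voom (248); without mouse 2 of the 24-month enriched group 438 had an unadjusted p under 0.05. Meningeal fibroblast genes had the smallest camera p with all libraries, with 17 of 18 above 0 (median 0.59, 5 adjusted over the list alone, camera adjusted p = 9.94e-09), then endothelial genes with 20 of 20 above 0 (median 0.25). At 24 months the meningeal level was high in enriched mice 3 and 4 (4.75 and 4.439, other enriched mice 3.498 to 3.749, controls 3.706 to 3.881). The endothelial level was highest in the same mice (4.798 and 4.922, other enriched mice 3.929 to 4.516, controls 3.935 to 4.55). camera called 14 lists higher and 6 lower, with an adjusted p of 0.647 to 0.86 with an estimated correlation. With RLE scaling it called 17 lists in all. Without the 2 libraries that stand apart the order changed: interferon genes, not called with all libraries (median -0.94), were higher with the smallest p (adjusted p = 1.92e-11), then reactive astrocyte (adjusted p = 5.93e-06) and meningeal genes (adjusted p = 6.83e-06). These camera values have the preset correlation only. Mouse 4 of the 5-month enriched group was left out after its interferon levels were seen, so the interferon p is no independent test. The exact test called none (lowest adjusted p = 0.982).

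Across 17527 genes, which are not independent replicates, the ageing change of control mice and the enrichment change at 24 months had r = -0.177. Both differences contain the 24-month controls with opposite sign, and over all 252 relabelings of the 24-month mice chance gave a mean r of -0.358 (-0.624 to -0.087; permutation p = 0.155). The covariance was -0.00645 against -0.0156 by chance, and with the controls split over the 20 ways r was 0.167 on average (-0.0497 to 0.349). Over genes with a mean of at least 5 CPM r was -0.0451 (permutation p = 0.0357). Without mouse 3 of the 24-month controls r was -0.198 (permutation p = 0.00794), and without mouse 2 of the 5-month controls -0.193 (permutation p = 0.0357). Each permutation p measures the distance from its own chance mean, not from 0. With all libraries that mean lay below r, so a small p does not show that enrichment opposed ageing. The enrichment changes at both ages had r = 0.102 (permutation p = 0.548, 63504 relabelings; covariance 0.00268), over mice with no overlap.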

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

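The tests of a wrong age label and of blood for mouse 4 of the 5-month enriched group, and the test of an effect of enrichment on the choroid plexus list in each mouse, were chosen after the result was seen. A mouse was taken to stand apart where its gap to the nearest of the other 4 in its group exceeded 0.71 of the group's range. Of 296 groups of values 25 held such a mouse, where chance gives about 15.

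Mouse 4 of the 5-month enriched group had interferon-induced and antigen presentation genes far above its group. Cxcl10, a chemokine that attracts T cells, stood at 17.8 CPM against 0.0383 to 1.03 CPM in the other 19 libraries, Ifit1 at 43.4 CPM against 1.49 to 3.92 CPM, the antibody light chain Igkc at 20.9 CPM against 0.0635 to 2.28 CPM and the astrocyte filament gene Gfap at 1520 CPM against 352 to 717 CPM. It held 6 of the 15 list levels that stood apart. Its levels against the other 4 mice were 4.48 for interferon response (1.27 to 1.63), 4.39 for MHC class I (2.45 to 2.84), 3.22 for reactive astrocytes (at most 2.32), 5.41 for cholesterol synthesis (5.07 to 5.12), 12.7 for mitochondrially encoded genes (12.1 to 12.2) and 6.06 for inhibitory neurons (6.37 to 6.43).

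For this mouse, a 24-month mouse under a 5-month label is argued against, since 93.8 percent of the 16 genes called between control mice of both ages lay nearer to the 5-month mean. Blood in the tissue is argued against as well: its red blood cell level of 2.17 was not above the highest of the other 4 (2.4), a difference of -0.23. A mix-up with a mouse of the same age or from outside the study stays open. An infection or another immune reaction in this mouse may explain the profile, but no biological explanation was tested, since the labels give no health record.

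Choroid plexus genes such as Ttr were called lower as a list in 24-month enriched mice with the preset correlation only (adjusted p = 0.972 with an estimated correlation, exact p = 0.365). The levels of 2 control mice (3.76 and 4.27) lay above all 5 enriched mice (1.15 to 2.01), and those of the other 3 (1.05, 1.08 and 1.83) did not. Tissue attached in some mice is a candidate explanation: after group means were removed, members of the list moved together, with a median correlation of 0.954 to the mean of the other members. Over all lists this median ran from 0.136 (neurotrophins and growth factors) to 0.971 (mitochondrially encoded genes), with 0.952 for oxidative phosphorylation and 0.942 for interferon genes. The correlation alone therefore cannot tell attached tissue from another shared change. Of the 23 tested choroid plexus members none is in another list, and 13 had at least 1 CPM even in the library with the lowest level, so hippocampal samples with little choroid plexus show some of them. Of the 5 enriched mice 0 lay below the lowest control mouse. This count cannot decide on an effect of enrichment in each mouse. The lowest control (1.05) lay near the lowest level of all 20 libraries (0.936), which left little room below it. An effect of housing stays open.

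Other mice stood apart in cell type lists. Mouse 5 of the 5-month enriched group had high levels of myelin genes (7.2, others 6.09 to 6.21), oligodendrocyte precursor genes (5.1, others 4.67 to 4.73) and neurogenesis genes (2.92, others 2.66 to 2.72). Among 5-month controls, mouse 4 was low in neurogenesis genes (2.43, others 2.76 to 2.86) and mouse 3 in myelin genes (5.81, others 6.4 to 6.63). Among 24-month controls, mouse 1 was low in reactive astrocyte genes (2.29, others 2.52 to 2.56), mouse 3 in interferon genes (1.3, others 1.61 to 1.7) and mouse 4 high in heat shock genes (5.82, others 5.66 to 5.69). Mouse 3 of the 24-month enriched group was high in cell cycle inhibitors and senescence genes (2.82, others 2.78 to 2.79). The total count of mouse 3 of the 5-month controls, in units of 1000000, was 37.4 (others 26.1 to 28.8).

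Of 136 groups of values for 34 genes 9 held a mouse that stood apart. The peptidase gene Naalad2 was high in mouse 3 of the 24-month controls (4.31 CPM, others 3.23 to 3.41) and in mouse 3 of the 24-month enriched group (4.57 CPM, others 3 to 3.13). Kif11 was high in mouse 5 of the 5-month enriched group (3.47 CPM, others 2.09 to 2.35), as was A530053G22Rik (0.16 CPM, others 0.0333 to 0.0652), while Trdn was low there (0.0533 CPM, others 0.166 to 0.196). Gm38340 was high in mouse 1 of the 24-month controls (3.89 CPM, others 1.81 to 2.34), Mlph in mouse 3 of the same group (4.56 CPM, others 3.55 to 3.82) and Fmo2 in mouse 4 of the 24-month enriched group (4.52 CPM, others 2.09 to 2.74). Pla2g4e was low in mouse 4 of the 5-month controls (4.36 CPM, others 6.26 to 6.67).

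The enrichment effect differed between both ages in 20 lists by camera with the preset correlation (17 with RLE scaling). None held with an estimated correlation (lowest adjusted p = 0.647), and the exact test called none (lowest adjusted p = 0.982). Without the 2 libraries that stand apart 8 of the 20 lost the call: astrocytes (adjusted p = 0.0742), oxidative phosphorylation (0.067), thalamus and habenula neurons (0.153), CA1 to CA3 pyramidal neurons (0.153), circadian clock (0.179), dentate gyrus granule cells (0.407), striatum and septum neurons (0.515) and ribosomal proteins (0.519). The differences in list level, 24 minus 5 months, were largest above 0 in meningeal fibroblasts (0.568), MHC class II (0.389), red blood cells (0.319), pericytes (0.295), striatum and septum neurons (0.256) and endothelium (0.253). In the meningeal, MHC class II, pericyte and endothelial lists, mice 3 and 4 of the enriched group had the highest levels of all 24-month mice. The differences in the other lists were smaller. These were 0.183 in glucocorticoid-responsive genes, 0.165 in collagens, 0.163 in immediate early genes, 0.138 in thalamus and habenula neurons, 0.113 in reactive astrocytes, 0.104 in CA1 to CA3 pyramidal neurons, 0.0915 in astrocytes and 0.0697 in circadian clock genes. They were -0.453 in the choroid plexus, -0.171 in ependyma, -0.122 in dentate gyrus granule cells, -0.0689 in heat shock genes, -0.0666 in ribosomal protein genes and -0.0413 in oxidative phosphorylation genes.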

How the results depend on the processing

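The robust fit, the covariates, the corrected RPKM values, the fit without 2 libraries and leaving out 5-month controls for the correlation of ageing and enrichment changes were chosen after the data were seen. Of the fold changes of named genes under all settings, 6457 kept direction and side of the threshold, 273 lost and 92 gained a call and 30 reversed. A gene called in neither fit counted as keeping its side, also in the 4 enrichment contrasts, where edgeR called 0 genes. The 6457 therefore do not measure how firm the calls were. Of the 87 calls with age in enriched mice, 9 were kept with the deposited RPKM values. The compared groups alone kept 14 and the covariates 25. For the 10 lists in control mice and 4 in enriched mice with an exact p under 0.05 for age, all 140 level differences with 1 library left out kept their direction (other lists are not in this count). No list passed the exact test with all libraries, so this says nothing about calls. In control mice between both ages, higher and lower genes numbered 19 and 8 with 1 surrogate variable and 53 and 25 with DESeq2, the deposited RPKM values gave 2 lower genes and a fit of the compared groups alone 9. Leaving out each library gave 6 to 14 higher genes. In enriched mice between both ages, higher and lower genes numbered 104 and 68 with 1 surrogate variable, 19 and 6 with choroid plexus and meningeal levels as covariates, 151 and 75 without the 2 libraries that stand apart, 160 and 114 with DESeq2, 9 and 1 with the deposited RPKM values and 12 and 3 with the compared groups alone. The corrected RPKM values gave 17 lower genes. Leaving out each library gave 19 to 155 higher and 6 to 83 lower genes, the most without mouse 4 of the 5-month enriched group. The cause of these shifts was not tested. For enrichment, edgeR called 0 genes in each of the 4 contrasts under every setting (main unadjusted counts 450, 323, 559 and 278, each below the 876 expected by chance). DESeq2 (413, 317, 530 and 244) and limma-voom (380, 298, 450 and 248) called 0 too. So did limma on the deposited RPKM values, with unadjusted counts of 1562, 238, 1167 and 271. With an estimated correlation, 0 lists were higher and 0 lower in each enrichment contrast, and 0 higher and 1 lower in each ageing comparison. Without the 2 libraries and with the preset correlation, 12 lists were higher and 9 lower with age in enriched mice. For the mean enrichment effect 2 were then higher and 3 lower.

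Interferon and immunoglobulin genes reversed with mouse 4 of the 5-month enriched group left out. Without the 2 libraries the log2 enrichment changes at 5 months were -0.262 for Cxcl10, -0.007784 for Ifit1, -0.07623 for Oasl2 and -0.8408 for Igkc. With each library left out they ranged from -0.2635 to 4.315, -0.008435 to 2.582, -0.07669 to 2.469 and -0.8417 to 4.034. For ageing in enriched mice the values without the 2 libraries were 0.2685 for Isg15, 0.5602 for Oasl2, 0.05442 for Oas1b and 0.9225 for Igkc. With each library left out they ranged from -2.182 to 0.2672, -1.985 to 0.5588, -1.636 to 0.05289 and -3.933 to 0.9202. For the difference of the enrichment effect Ifit3b was 0.09043 without the 2 libraries, and -2.181 to 0.1205 with each left out. The deposited RPKM values, which moved the median change of all genes by 0.148 for enrichment at 5 months, 0.142 for ageing in control mice and -0.131 for the difference of effects, gave 0.02397 for Cdh24 and 0.008717 for Pdk4 (enrichment at 5 months). They gave 0.009969 for Myl9, 0.002054 for Hapln1 and 0.03015 for Trp53inp1 (ageing in control mice), and 0.1056 for Lrrc45 and 0.1022 for Tef (mean enrichment effect). With the covariates, Slc22a6 was -0.06156 and Ttr 0.02688 (enrichment at 24 months), Tmem72 0.2071 and Ttr 0.0109 (mean effect), and Col1a2 -0.07027 (difference of effects). The correlation of ageing and enrichment changes was -0.0451 over genes with a mean of at least 5 CPM (permutation p = 0.0357). It ranged from -0.3 to -0.121 with each of the 15 libraries left out. It was -0.198 without mouse 3 of the 24-month controls (permutation p = 0.00794) and -0.193 without mouse 2 of the 5-month controls (permutation p = 0.0357). These p-values measure the distance from the chance mean, not from 0. With all libraries that mean was -0.358 and lay below r (-0.177), so a small p does not show that enrichment opposed ageing. No paired analysis was possible because the labels give no replicate number, litter or batch shared between groups.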

Other observations

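The genes of the first paragraph, the correlation of both ageing changes, the test of order along the protocadherin row and the test of the alpha and gamma protocadherins were chosen after the values were seen. In enriched mice, Cirbp, an RNA-binding protein induced by cold, rose with age from 57.3 ± 7.62 to 87.2 ± 7.41 CPM (log2 0.61 ± 0.10, edgeR adjusted p = 0.00713), and in control mice it stood at 0.48 ± 0.10 (adjusted p = 0.0651). Rbm3, its cold-induced relative, was at 0.11 ± 0.13 (adjusted p = 0.817). Neat1, the long noncoding RNA that builds paraspeckles, rose from 156 ± 27.3 to 256 ± 37.4 CPM (0.72 ± 0.14, adjusted p = 0.0233). Among single genes of Polycomb proteins, which silence chromatin, Cbx7 (0.22 ± 0.04, adjusted p = 0.0214) and Pcgf2 (0.38 ± 0.09, adjusted p = 0.0486) rose, and Cbx8 fell (-0.47 ± 0.10, adjusted p = 0.0486). Pcdh12, a protocadherin of endothelial cells, fell (-1.33 ± 0.25, adjusted p = 0.0178), and Plvap, which forms the diaphragms of leaky vessels, rose (0.55 ± 0.12, adjusted p = 0.0424). Plvap overlaps Gtpbp3, and Cbx7 overlaps Apobec3, on the opposite strand, so both are uncertain. These changes passed in enriched mice and not in control mice, but none differed between both housings past the threshold.

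Across 17527 genes, which are not independent replicates, the ageing changes of control and enriched mice had r = 0.565 (permutation p = 0.000126, 63504 relabelings, chance range -0.601 to 0.601) and a covariance of 0.0305 against 0 by chance. The r was 0.49 to 0.581 with each library left out. The groups compared share no mouse.

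The change of the beta protocadherins with age was larger toward the start of their row (Spearman -0.808, permutation p = 2e-05 over 100000 permutations, Pearson -0.781). These permutations move genes, which are neighbours and not independent replicates, rather than mice. As the order had been seen before, this p describes the pattern and is no independent test of it. A bias from gene length or expression level is argued against, since 0 percent of 10000 random sets matched on both reached the median of 0.297 (highest 0.135). A larger share of neurons in old samples is argued against, since the 32 alpha and gamma protocadherins, which neurons also express, had a median of -0.0526 (SD 0.242). Reads shared between paralogs cannot be told apart from a change of each gene: the rise had a Spearman correlation of -0.0514 with the share of 50-base words (permutation p = 0.82), within its spread of 0.218. A change in the regulation of this end of the cluster with age may underlie the rise, as a hypothesis drawn from these same data. Regulation itself was not tested.

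Liver transcripts were found in mouse 5 of the 24-month controls: Alb stood at 68.2 CPM (other libraries 1.6 to 17.4), Mup3 at 13.3 CPM (0.0833 to 1.49), Fabp1 at 6.48 CPM (0.0317 to 0.815) and Apoa1 at 5.89 CPM (0.23 to 1.23). Of the 13 protein-coding mitochondrial genes 4 (mt-Co2, mt-Atp8, mt-Atp6 and mt-Nd4l) had 0 counts in every library, and mt-Co3 and mt-Nd3 had at most 1.

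Mice were regrouped in 100 splits per comparison, the real one included. For ageing in control mice the splits alone do not exclude chance as the source of the number of genes: 6 of the 100 called at least the 16 genes of the real one, and the highest other called 95. For the genes at an unadjusted p under 0.05 they do not exclude it either, since 13 gave at least the real 1469 (highest other 3849). The genes themselves recurred in other mice, with 10 of the 12 higher and 3 of the 4 lower ones also called with age in enriched mice, where independent lists would share 0.0411 and 0.00616. Both comparisons came from the same fit, so these calls are not independent. A difference between the mice of both ages other than age would recur in both housings too, so the recurrence does not decide the question. In each of the 5 other splits that called at least 16 genes, the 4 control mice with the highest choroid plexus levels (at least 3.76, the next 2.08) stood on the same side. These 4 did so in 6 of all 99 other splits, a comparison made after the splits were seen. For ageing in enriched mice 2 of 100 splits, the real one included, called at least 87 genes, below the limit set beforehand. The other of the 2 called far more, so the splits make chance less likely for this number but do not exclude it. Nor do they for the genes at an unadjusted p under 0.05, where 13 gave at least the real 2063 (highest other 4759). The other split that called at least 87 genes called 1449. It set mice 4 and 5 of the 5-month group with mice 2, 4 and 5 of the 24-month group against the rest. As seen afterwards, its sides also separated in ribosomal protein level (3.971 to 4.275 against 3.78 to 3.809). They did so too in oxidative phosphorylation level (6.159 to 6.383 against 6.035 to 6.062), which points to a structure of the samples beyond age. What lies behind it was not tested. Only 26 of the 87 calls were kept without mouse 1 of the 5-month enriched group, and as many without its mouse 2. For enrichment, chance cannot be excluded for the genes at an unadjusted p under 0.05. At 5 months 88 of 100 splits gave at least the real 450 (highest other 4453), at 24 months 87 gave at least 323 (3641), for the mean of both ages 66 gave at least 559 (3718) and for the difference of effects 91 gave at least 278 (5479). In the 5-month split with 4453 genes the sides again separated in ribosomal protein level (3.89 to 4.239 against 3.728 to 3.859). The highest counts of the other splits too point to a structure of the samples that housing does not explain.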
